A study of Homo sapiens with 23 samples.

How the data were processed

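Platelets isolated from platelet-rich plasma of people with familial hypercholesterolemia (FH) and of healthy people were profiled by bulk RNA-seq. Per the labels' protocols, RNA was extracted with a column kit, messenger RNA was enriched with oligo(dT) beads, and directional libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7 and aligned with STAR 2.7.9a to hg38. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. The deposited values are raw counts per gene, whole numbers for 58219 versioned Ensembl gene IDs in 23 libraries, with no normalization by the authors. Gene symbols were matched for 41805 IDs from a table of gene names, and GENCODE release 29 placed 57881 IDs on GRCh38 (55050 with the same version). This release may not be the one the authors used. SOD2 was not matched to a symbol and is missing from its list.

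Groups and replicate numbers came from the labels. Library identifiers in the labels start with one of 2 numbers. These were taken here as project numbers, a name that the labels do not give. The first project holds 4 FH and 2 healthy libraries and the second 9 FH and 8 healthy libraries, so the project was a model term and results were repeated within the second project. The study's design text speaks of 12 to 13 replicates per condition, and 10 healthy libraries were analysed here. Sex, age and treatment were not modelled. Total counts ranged from 20527890 to 69072499 per library, so counting error is small beside the spread between libraries (biological coefficient of variation 0.478). No 2 libraries of one group were identical, and the lowest chi-square per degree of freedom over the 123 pairs of libraries of one group was 46.8, so none was counted as a duplicate.

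The choices below were fixed before the data were examined unless stated otherwise. Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), scaled by TMM (factors from 0.366 to 2.65) and tested with a robust quasi-likelihood fit of project and group. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The median log2 fold change over all tested genes was -0.06, and other scalings moved it by less than 0.1. These scalings place most genes near no change, so this median does not test them. The TMM factors were 0.889 ± 0.409 in FH and 1.436 ± 0.642 in healthy libraries, so the size of each change depends on the scaling. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are TMM-scaled CPM of the tested genes. Chromosome Y genes, XIST and TSIX were tested (17 genes) but their rows were left out. The 25 gene lists were tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, again with the correlation estimated, and with fry. Fry, which asks whether a list's genes move on balance one way and makes no comparison with other genes, gave adjusted p-values under 0.05 for 20 lists and not for nuclear oxidative phosphorylation, proteasome, interferon-stimulated, endoplasmic reticulum stress and B cell genes. The value given for a list is the median edgeR log2 fold change of its members. PLSCR3, GP1BB, APOC1, OLR1, CHAC1, GYPB, CDH5 and KDR were among the members below the filter. Markers of other cell types are also expressed in platelets or shared between cell types to a degree that was not tested.

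The genes named were chosen by a rule: in each direction the 8 largest fold changes and the 6 smallest p-values among others at adjusted p under 0.05, with a mean of at least 2 CPM in one group and the same sign in each project alone; the 3 members of smallest p of each list, or 2 for lists of cell markers; and BCL2L1, BAX, BAK1, SCARB1, PF4 and PTPRC in any case. Some genes that this rule names are not reported here. XIST, chromosome Y genes and antigen receptor segments were never named.

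For each library the share of counts from 13 mitochondrial protein genes and 2 mitochondrial rRNAs, the share from 5 haemoglobin genes, the share of the 10 most counted genes, the genes detected after thinning to the smallest library's total, and the PTPRC level as log2(CPM + 1) were computed. Group means were compared by two-sided permutation tests in scipy 1.17.1 (100000 resamples; exact within the second project), and adjusted over 6 measures, the last being the mitochondrial share outside rRNA.

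The edgeR procedure was tested on simulated counts for 15874 genes with the real means and library sizes, in which 200 genes were changed and 40 more were raised 2-fold as a list. It recovered 7.46% of genes changed by 1.5-fold, 55.2% by 2-fold and 92.4% by 4-fold, and 5.22% of its calls were unchanged genes. The simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.957. These rates may therefore not hold for the real data. Alternatives were a fit with no project term, the second project only, size factors of DESeq2 1.42.0, the DESeq2 Wald test, voom with sample quality weights, no filter, a stricter filter (1 CPM in at least 10 libraries), PTPRC as a covariate, 4 surrogate variables from sva 3.50.0, removal of haemoglobin and mitochondrial genes, a replicate block, and leaving out each library. Chosen after the data were seen were fits with a platelet identity score or with platelet, T and NK cell and neutrophil scores as covariates (mean log2 CPM of those lists), and a fit without the 5 libraries of lowest platelet score. The score fits were applied to counts, lists, gene families and the apoptosis genes that had passed, and to other named genes only as a summary. This scope was set after the gene values of these fits were seen.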

Results

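The study compared the RNA of blood platelets between people with familial hypercholesterolemia (FH), an inherited disorder that raises low-density lipoprotein cholesterol, and healthy people. Its stated question is how high-density lipoprotein (HDL) maintains and protects platelets, and its title names platelet apoptosis and thrombus formation. Platelets carry RNA inherited from the megakaryocytes that shed them, and each library is bulk RNA-seq of 1 platelet preparation. Whether every library comes from a separate person is not given in the sources used here beyond the words biological replicates. There were 13 FH and 10 healthy libraries. The deposited values were raw counts per gene. The libraries fell into 2 sets by the number that starts their identifiers, and these sets are called projects here. The first held 4 FH and 2 healthy libraries with 20527890 to 34421192 counts each. The second held 9 FH and 8 healthy libraries with 45381403 to 69072499. No 2 libraries of one group were identical. The project entered the main model as a term. Every change below is a log2 fold change of FH over healthy with its standard error, and levels are TMM-scaled CPM, mean ± SD over 13 FH and 10 healthy libraries. Positions are on GRCh38.

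All 16 neutrophil markers tested were higher in FH platelet preparations than in healthy ones, and 12 of 19 T and NK cell markers were lower. Camera called both lists at its preset correlation and neither with an estimated correlation (adjusted p = 0.25 and 0.29). Of 16692 genes tested, 2517 (15.1%) were higher and 2950 (17.7%) were lower in FH (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The counts of members that passed in each list below were not tested against these shares. A change of at least 2-fold was reached by 1387 of the higher and 787 of the lower genes. In the second project alone, 2744 genes were higher and 1957 lower. Of the second project's calls that were also tested in the first, 93.6% of the higher (2501 of 2673) and 90.9% of the lower (1718 of 1889) had the same direction there, against 49.6% and 50.4% of all genes. Over all 15530 genes tested in both projects, called or not, 78.2% had the same sign in both. The first project alone, with only 2 healthy libraries, gave 0 calls by edgeR, with 772 of 16905 genes at an unadjusted p under 0.05. The counts changed with the libraries used and with cell scores in the model. Leaving out FH replicate 10 gave 4116 higher genes, leaving out healthy replicate 4, 5 or 7 gave 1673, 1570 or 1705 lower genes, and, in alternatives chosen after the data were seen, 1182 genes were higher and 683 lower with a platelet identity score in the model, 529 and 184 without the 5 libraries of lowest platelet score, and 1 and 0 with platelet, T and NK cell and neutrophil scores in the model.

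The largest increases in FH, among genes chosen by a fixed rule, ranged over enzymes, an inhibitor and transcriptional regulators. PRSS33, a serine protease (ENSG00000103355, chromosome 16, 2783953 to 2787948), rose by 5.26 ± 0.70, from 0.0680 ± 0.117 to 2.38 ± 2.67 CPM (adjusted p = 0.00020). ALOX15, the 15-lipoxygenase that oxidises polyunsaturated fatty acids (chromosome 17, 4630902 to 4642294), rose by 4.84 ± 0.63, and PI3, the elastase inhibitor elafin, rose by 4.33 ± 0.68. The Polycomb gene PCGF2 (4.32 ± 0.78), the matricellular gene CCN3 (4.31 ± 0.84), the carbonic anhydrase gene CA4 (4.30 ± 0.84) and the immediate early transcription factor EGR2 (4.17 ± 0.71) rose by similar amounts. EGR2 went from 0.547 ± 0.566 to 9.94 ± 8.22 CPM. The largest fold of all, 5.51 ± 1.67 for the pseudogene MTND1P23, rested on 1 library: it was 1.30 without FH replicate 10, and this gene shares sequence with mitochondrial DNA, so its counts are uncertain. The smallest p-value of all belonged to AATK, a kinase gene named for its association with apoptosis (ENSG00000181409, chromosome 17, 81117295 to 81166077),, which rose by 2.31 ± 0.25, from 6.12 ± 2.05 to 30.2 ± 12.6 CPM (adjusted p = 2.9e-05). With the largest folds set aside, C15orf39 (1.51 ± 0.18), the interferon gamma receptor subunit IFNGR1 (1.28 ± 0.17), the arrestin-domain gene ARRDC4 (1.76 ± 0.24), the peptidylarginine deiminase PADI2 (3.68 ± 0.50) and TMCC3 (2.13 ± 0.29) followed. Beside these genes, the neutrophil markers had a median change of 3.23 and the basophil and eosinophil markers one of 1.78. PRSS33 and ALOX15 were highest in FH replicate 7 (9.99 and 15.61 CPM) and next highest in FH replicate 11. The basophil and eosinophil markers IL5RA and SIGLEC8 had the same order (5.388 and 2.95 CPM in FH replicate 7). Which cells the transcripts of the largest increases came from was not tested.

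The largest decreases in FH, chosen by the same rule, included chemokine and orphan receptors. CXCR6, a chemokine receptor of T and NK cells (ENSG00000172215, chromosome 3, 45940933 to 45948353), fell by 2.82 ± 0.40 on the log2 scale, from 2.36 ± 1.30 to 0.306 ± 0.207 CPM (adjusted p = 0.00020). The receptor GPR171 (-2.16 ± 0.32), CNTNAP1 (-2.16 ± 0.44) and NPDC1 (-2.15 ± 0.38) also fell. WDR86-AS1 (-2.30 ± 0.41) is an antisense gene whose counts depend on a strand setting that is not given in the sources used here. HLA-DRB5 (-2.21 ± 0.68) shares reads with other HLA-DRB genes, and both it and WDR86-AS1 are uncertain. HLA-DRB5 ranged from 0.1807 to 20.34 CPM in FH and from 0.9277 to 56.3 CPM in healthy libraries. What sets this spread within each group was not tested. Among the smallest p-values were GIMAP7, a GTPase of lymphocytes (-1.46 ± 0.20, from 59.0 ± 27.9 to 19.1 ± 7.58 CPM), NMT2, which attaches myristate to proteins (-1.12 ± 0.16), the caspase-like pseudogene CASP4LP (-1.64 ± 0.23, uncertain because of its paralogs), the Wnt pathway gene PYGO2 (-0.97 ± 0.15), the chaperone HSPH1 (-0.99 ± 0.15) and the cytokine signalling inhibitor CISH (-1.82 ± 0.28). Beside these genes, the T and NK cell markers had a median change of -1.17.

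Apoptosis genes changed in both directions and on both sides of the pathway. Of all genes tested, 15.1% rose and 17.7% fell, so counts near these shares are not particular to apoptosis genes. Of 31 pro-apoptotic genes tested, 6 rose, 2 fell and 23 did not pass (5 and 2 adjusted over the list alone), with a median change of 0.37. BID, which links death receptors to mitochondria (ENSG00000015475, chromosome 22, 17734138 to 17774770), rose by 1.08 ± 0.21, from 19.9 ± 8.96 to 42.1 ± 8.97 CPM (adjusted p = 0.0012). The tumour necrosis factor receptor TNFRSF1A (1.29 ± 0.31) and the apoptosome gene APAF1 (0.66 ± 0.18) rose as well. Of 12 anti-apoptotic genes, 5 rose, 2 fell and 5 did not pass (6 and 3 adjusted over the list alone), with a median of 0.55. CFLAR, an inhibitor of caspase 8 activation, rose by 0.82 ± 0.17, MCL1 rose by 0.98 ± 0.26 from 222 ± 78.0 to 433 ± 222 CPM, and BIRC3 fell by 1.03 ± 0.28. BCL2L1, which encodes the survival factor BCL-XL that sets platelet lifespan (ENSG00000171552, chromosome 20, 31664452 to 31723989), rose by 0.91 ± 0.34, from 230 ± 141 to 440 ± 203 CPM (adjusted p = 0.045). Its call was lost on leaving out any of FH replicates 1, 2, 5, 7, 11, 12 and 13 or healthy replicates 2, 6, 9 and 11, with adjusted p up to 0.089. The effectors BAX (0.13 ± 0.15, adjusted p = 0.48) and BAK1 (-0.10 ± 0.16, adjusted p = 0.62) did not pass. Other members that passed, named after their values were seen, were BMF (0.64 ± 0.18), BBC3 (0.63 ± 0.23), BAD (0.82 ± 0.31), TRADD (-0.46 ± 0.13), BCL2A1 (1.85 ± 0.50), BAG1 (0.72 ± 0.19) and BCL2 (-0.70 ± 0.22). Each list passed camera at its preset correlation (adjusted p = 0.048 for both), and neither held with an estimated correlation (adjusted p = 0.29 for both). The pro-apoptotic call was lost on leaving out FH replicate 1, 3, 5, 9 or 13 or healthy replicate 2, 6 or 11 (adjusted p up to 0.058, medians 0.25 to 0.50 over all 23 such fits). The anti-apoptotic call was lost on leaving out FH replicate 1, 2, 3, 4, 9, 10, 11, 12 or 13 or healthy replicate 1, 2, 5, 6, 7 or 9 (adjusted p up to 0.066, medians 0.44 to 0.75). With the platelet identity score in the model, 6 of the 15 members that had passed still passed. Those were BID, TNFRSF1A, APAF1, BMF, CFLAR and MCL1. With the platelet, T and NK cell and neutrophil scores in the model 0 of 15 passed by edgeR. Over all genes, that fit called 1 higher and 0 lower, and 1531 had an unadjusted p under 0.05. With the platelet identity score alone, BCL2L1 changed by 0.154 ± 0.098 (edgeR adjusted p = 0.32).

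**Figure D1:**
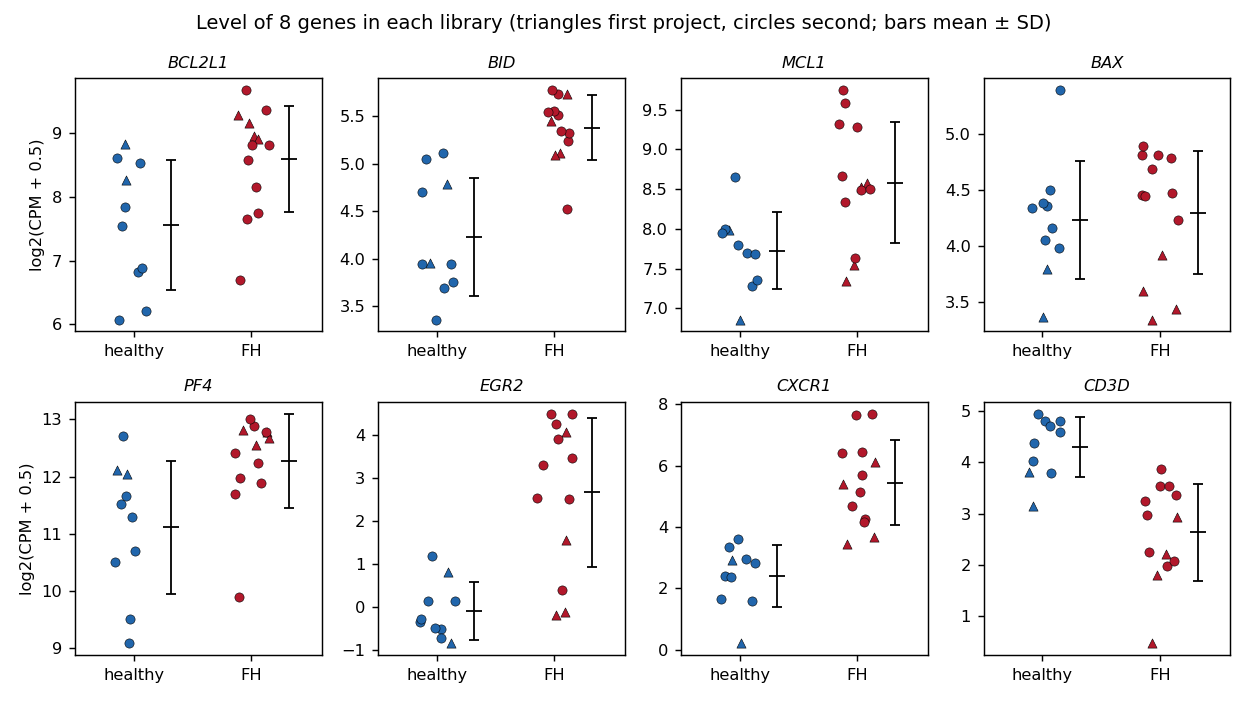
Level of 8 genes in each library as log2(CPM + 0.5), with healthy libraries in blue (n = 10), FH libraries in red (n = 13), triangles for the first project, circles for the second, and bars for the mean ± SD of each group. BID, MCL1, EGR2 and CXCR1 lay higher and CD3D lay lower in FH, BCL2L1 passed narrowly (adjusted p = 0.045), and PF4 and BAX did not pass.

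Lists of platelet function had positive median changes in FH. Their counts stand beside 15.1% of all genes tested that rose and 17.7% that fell, and were not tested against these shares. Of 17 genes of phosphatidylserine exposure, the membrane change that makes platelets procoagulant, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.61. XKR8, a caspase-activated scramblase, rose by 1.54 ± 0.25, from 4.397 ± 1.028 to 12.6 ± 7.30 CPM, coagulation factor V (F5) rose by 1.61 ± 0.34, and the scramblase gene PLSCR1 rose by 0.95 ± 0.21. Of 41 platelet receptor and signalling genes, 8 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.61. They included the Fc receptor FCGR2A (2.19 ± 0.40, which has near-identical paralogs), the thromboxane synthase TBXAS1 (1.25 ± 0.25) and CLEC1B, the receptor CLEC-2 (1.23 ± 0.34). XKR8, FCGR2A and the neutrophil marker CXCR1 all had their lowest FH levels in FH replicates 3, 4 and 12. There XKR8 was at 5.455, 2.444 and 5.815 CPM and the platelet gene PF4 at 7046, 6552 and 4801 CPM. Whether XKR8 and FCGR2A rose in platelet or in neutrophil RNA was not tested. Of 35 granule genes, 7 rose and 1 fell (4 and 0 adjusted over the list alone), with a median of 0.75, among them STX11 (0.92 ± 0.25) and the granule proteoglycan SRGN (1.06 ± 0.31). Platelet factor 4 (PF4) was at 5532 ± 2076 CPM in FH and 2844 ± 1911 CPM in healthy libraries, a change of 0.92 ± 0.38 that did not pass (adjusted p = 0.062) and that passed on leaving out FH replicate 4 or 10 or healthy replicate 10. PF4 also passed with the DESeq2 Wald test (adjusted p = 0.021), voom with sample quality weights (adjusted p = 0.0068), PTPRC as covariate (adjusted p = 0.0042) and without haemoglobin and mitochondrial genes (adjusted p = 0.045). Of 26 platelet identity genes, 5 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.80, including TUBA8 (1.21 ± 0.36), FLI1 (0.63 ± 0.20) and ACRBP (1.02 ± 0.35). Camera gave adjusted p-values of 0.0011, 2.1e-06, 2.7e-04 and 7.5e-06 for the 4 lists in this order, and none held with an estimated correlation (adjusted p = 0.25, 0.37, 0.37 and 0.38). With the platelet identity score in the model, the medians of the lists of phosphatidylserine exposure, receptors and granules were 0.04, 0.02 and -0.04, and none of these 3 passed. That score shares ITGA2B and GP9 with the receptor list and PF4 and PPBP with the granule list. The fall of the receptor and granule medians is therefore partly built into the fit and does not show its cause.

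Cholesterol genes changed in both directions, and most did not pass. Of 24 genes of sterol synthesis, 2 rose and 5 fell (2 and 5 adjusted over the list alone), with a median of -0.17 that did not pass camera (adjusted p = 0.17, or adjusted p = 0.53 with an estimated correlation). Leaving out each library in turn gave sterol medians from -0.289 to -0.056, and the list passed in no such fit. HSD17B7 (-0.86 ± 0.20), ACAT2 (-0.59 ± 0.14) and the lanosterol synthase LSS (-0.81 ± 0.20) fell. The HDL receptor gene SCARB1 changed by 0.22 ± 0.25 (adjusted p = 0.47). Of 20 genes of lipoprotein uptake, cholesterol efflux and storage, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.39 and a camera adjusted p of 0.049, or adjusted p = 0.27 with an estimated correlation. This call was lost on leaving out healthy replicate 2 or 11 or FH replicate 1, 3, 4, 5, 6, 8, 9, 10, 11, 12 or 13 (adjusted p up to 0.14), and the median was 0.22 without FH replicate 5, 0.21 without FH replicate 9 and 0.26 without healthy replicate 1. They included APOE (1.76 ± 0.49, below 0.4 CPM in both groups' means) and the cholesterol efflux pump ABCA1 (1.19 ± 0.42, from 5.12 ± 2.85 to 11.7 ± 8.54 CPM). The call of ABCA1 was lost on leaving out FH replicate 2, 8 or 13 or healthy replicate 1, 6 or 7 (adjusted p up to 0.071) and with no filter (adjusted p = 0.087). With the platelet identity score in the model the median of this list was 0.17, and it did not pass (adjusted p = 0.095).

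Mitochondrially encoded transcripts had a median change of 0.97, with 1 of 13 genes passing (0 adjusted over the list alone). That gene was MT-ND5 (1.06 ± 0.40, adjusted p = 0.046, lost in 14 of the 23 fits that left out 1 library), and MT-ND3 (1.05 ± 0.41) and MT-ND4L (1.01 ± 0.41) did not pass. The list passed camera (adjusted p = 3.5e-04, or adjusted p = 0.38 with an estimated correlation), and its median was 0.08 in the first project and 1.33 in the second. With the 3 cell scores in the model its median was -0.95 and camera called it lower in FH (adjusted p = 2.6e-06, or adjusted p = 0.64 with an estimated correlation). Of 71 nuclear genes of oxidative phosphorylation, 6 rose and 5 fell (1 and 1 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.14, or adjusted p = 0.77 with an estimated correlation). NDUFA5 rose by 1.17 ± 0.30, NDUFC1 rose by 0.68 ± 0.21 and NDUFA13 changed by -1.12 ± 0.30. Of 80 cytosolic ribosomal protein genes, 0 rose and 16 fell (0 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 2.3e-06, or adjusted p = 0.50 with an estimated correlation). RPL22 (-0.46 ± 0.15) and RPL32 (-0.53 ± 0.18) were among the members of smallest p, and many of these genes have processed pseudogenes that can share reads. Of 37 proteasome genes, 2 rose and 4 fell (0 and 1 adjusted over the list alone), among them PSMC6 (-0.34 ± 0.09), with a median of 0.01 while the camera test leaned down (adjusted p = 0.99, or adjusted p above 0.99 with an estimated correlation).

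Immediate early genes had the fourth highest median of the 25 lists. Of 19 immediate early genes, which are switched on within minutes of a stimulus, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.501 (camera adjusted p = 5.4e-06, or adjusted p = 0.29 with an estimated correlation). BTG2 rose by 1.70 ± 0.38, from 52.5 ± 32.7 to 171 ± 90.3 CPM, and IER2 rose by 1.49 ± 0.37. The median of this list was 0.04 in the first project and 1.98 in the second. Of 26 NF-kB and inflammatory genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 3.9e-05, or adjusted p = 0.29 with an estimated correlation). The interleukin 1 receptor antagonist IL1RN rose by 2.48 ± 0.47, the endotoxin receptor TLR4 rose by 2.08 ± 0.43 and ICAM1 rose by 1.75 ± 0.38. With the 3 cell scores in the model the median of the immediate early list was -0.67 and did not pass (adjusted p = 0.15). In that fit the NF-kB list had a median of -0.57 and was called lower (adjusted p = 6.4e-04, or adjusted p = 0.64 with an estimated correlation). Of 32 autophagy and mitophagy genes, 15 rose and 2 fell (18 and 3 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 3.5e-04, or adjusted p = 0.29 with an estimated correlation). They included the initiating kinase ULK1 (0.94 ± 0.17), the lysosomal gene LAMP2 (1.13 ± 0.22) and PINK1, a kinase of mitophagy (0.95 ± 0.21, from 11.7 ± 3.66 to 22.5 ± 9.92 CPM). Of 24 antioxidant genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.0025, or adjusted p = 0.37 with an estimated correlation). Catalase (CAT, 0.92 ± 0.23), thioredoxin (TXN, 0.93 ± 0.24) and SRXN1 (1.26 ± 0.37) rose. With the platelet identity score in the model the antioxidant median was 0.038 and did not pass (adjusted p = 0.33), and with the 3 cell scores the antioxidant and autophagy medians were -0.15 and -0.033. Interferon-stimulated genes moved both ways, with 4 of 39 higher and 6 lower (4 and 6 adjusted over the list alone). IFITM2 rose by 1.88 ± 0.30 whereas USP18 (-1.40 ± 0.27) and OAS2 (-0.79 ± 0.17) fell, and the list had a median of -0.10 but a mean of 0.01 (camera adjusted p = 0.77, or adjusted p = 0.97 with an estimated correlation). Endoplasmic reticulum stress genes also split, with 5 of 26 higher and 5 lower (6 and 7 adjusted over the list alone) and a median of -0.24 (camera adjusted p = 0.73, or adjusted p = 0.93 with an estimated correlation). Leaving out each library in turn gave medians of this list from -0.277 to -0.124, and it passed in no such fit. DDIT3 (1.32 ± 0.36), DNAJC3 (0.70 ± 0.20) and SEL1L (0.44 ± 0.12) rose.

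**Figure D2:**
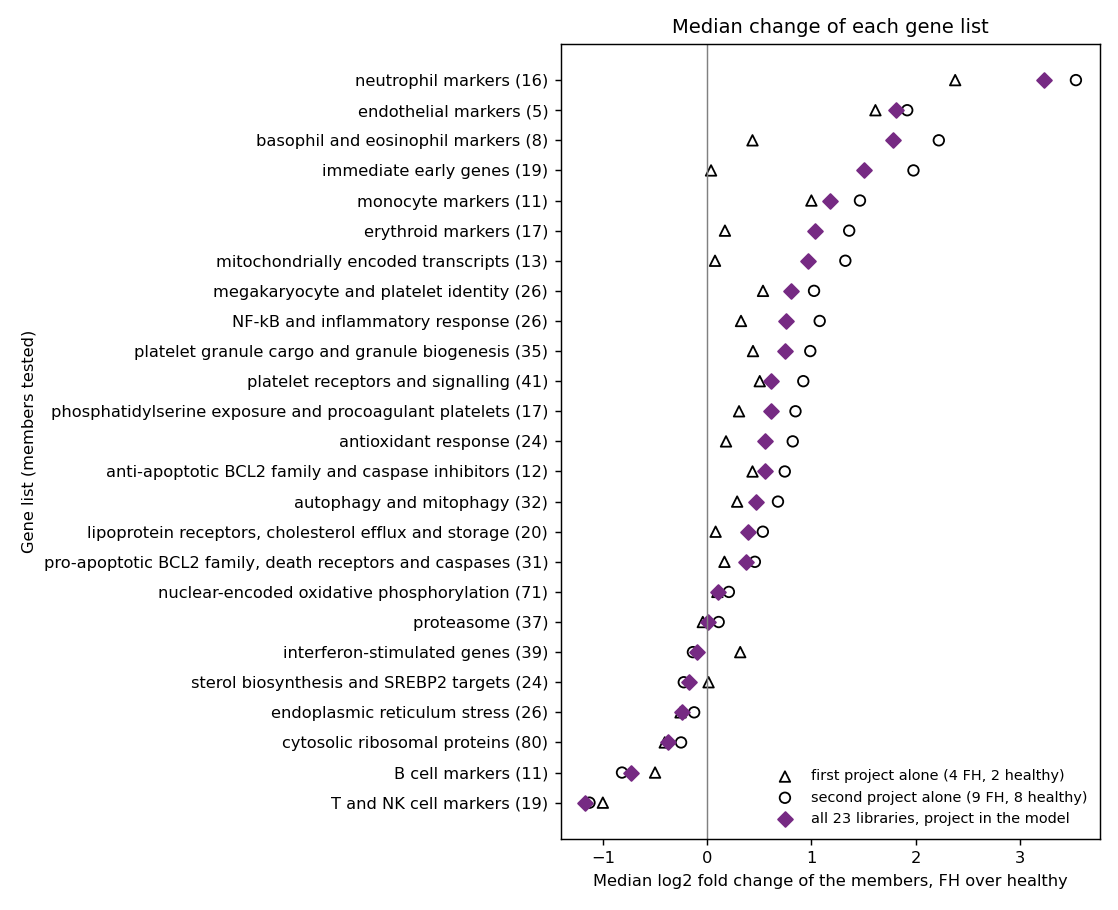
Median log2 fold change (FH over healthy) of each of the 25 gene lists, with the number of members tested in brackets, for all 23 libraries with the project in the model (diamonds) and for each project alone (triangles, first; circles, second). Neutrophil markers had the highest median of these lists (3.23) and T and NK cell markers the lowest (-1.17), and both kept their direction in each project.

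The lists of markers of other cells, except that of B cells, held genes that passed, and these lists changed in different directions. All 16 neutrophil markers rose (16 adjusted over the list alone), with a median of 3.23. The chemokine receptor CXCR1 rose by 3.56 ± 0.54, from 5.76 ± 3.41 to 66.4 ± 66.8 CPM, and the metalloprotease MMP25 rose by 3.69 ± 0.56, from 9.24 ± 6.84 to 123.1 ± 109.1 CPM. Of 11 monocyte markers 8 rose (9 adjusted over the list alone), with a median of 1.18, including CD14 (2.12 ± 0.48) and CLEC12A (1.59 ± 0.40). Of 8 basophil and eosinophil markers 5 rose (6 adjusted over the list alone), with a median of 1.78, including IL5RA (2.29 ± 0.43) and SIGLEC8 (3.36 ± 0.64), and the median was 0.43 in the first project and 2.22 in the second. Of 17 erythroid markers 8 rose (11 adjusted over the list alone), with a median of 1.03, including HBM (1.53 ± 0.47) and CA1 (1.27 ± 0.40), and the median was 0.17 in the first project and 1.36 in the second. Of 5 endothelial markers 4 rose (5 adjusted over the list alone), with a median of 1.81, and the means of TEK (0.629 ± 0.379 CPM in FH) and ERG (1.10 ± 0.457 CPM in FH) were low. Of 19 T and NK cell markers 12 fell (15 adjusted over the list alone), with a median of -1.17. CD3D fell by 1.49 ± 0.27, from 20.6 ± 7.44 to 6.86 ± 3.97 CPM, and the T cell receptor constant gene TRAC fell by 1.48 ± 0.29. None of the 11 B cell markers passed (0 adjusted over the list alone), with a median of -0.73 and CD22 at -0.73 ± 0.29 (adjusted p = 0.057). In the order neutrophil, monocyte, basophil and eosinophil, erythroid, endothelial, T and NK cell, and B cell, camera gave adjusted p-values of 2.0e-14, 7.3e-05, 2.1e-06, 7.5e-06, 3.5e-04, 9.9e-07 and 0.048. With an estimated correlation the adjusted p-values were 0.25, 0.29, 0.25, 0.29, 0.25, 0.29 and 0.53, so none held. PTPRC, the leukocyte gene for CD45, changed by 0.06 ± 0.19 in the edgeR test (adjusted p = 0.82).

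**Figure D3:**
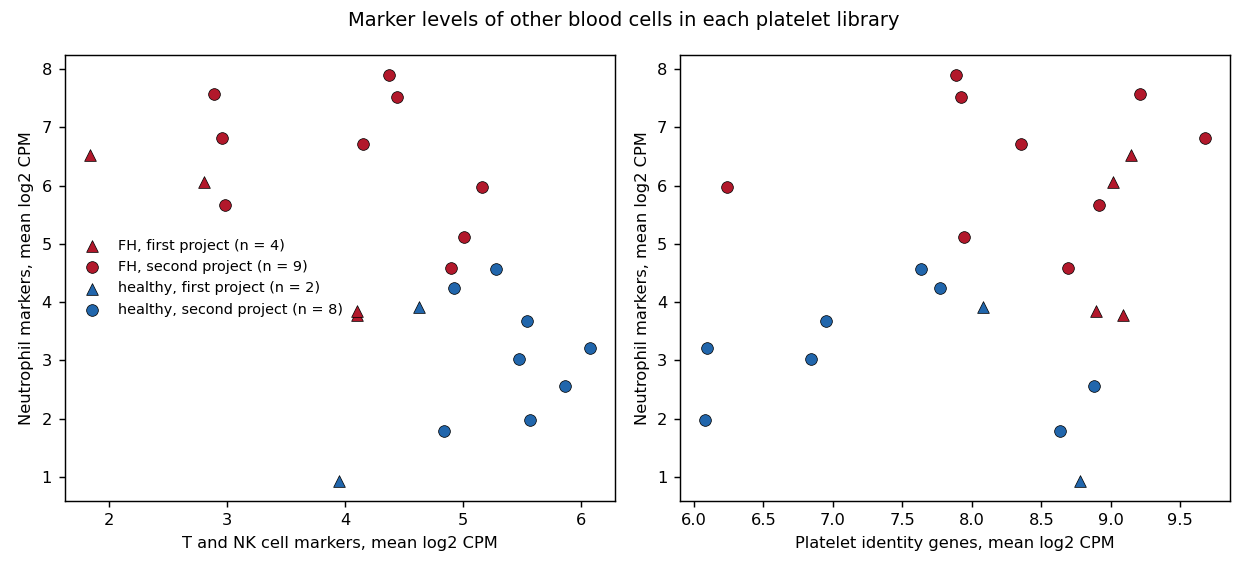
Mean log2 CPM of the neutrophil markers in each library against that of the T and NK cell markers (left) and of the platelet identity genes (right), with FH in red (n = 13), healthy in blue (n = 10), triangles for the first project and circles for the second. Neutrophil markers lay between 3.78 and 7.90 in FH and between 0.94 and 4.57 in healthy libraries, and the lowest platelet identity levels were those of healthy replicates 5 (6.08) and 4 (6.09) and FH replicate 10 (6.24).

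Coarse measures of the libraries differed less between the groups. Mitochondrial genes took 39.2 ± 21.2% of counts in FH and 34.3 ± 16.9% in healthy libraries (two-sided permutation p = 0.55, adjusted over 6 measures p = 0.55). Within the second project these shares were 51.9 ± 9.08% (n = 9) and 39.6 ± 13.8% (n = 8; exact permutation p = 0.048, adjusted p = 0.14), and in the first project they were 7.63 to 14.5% in FH and 5.66 to 20.9% in healthy libraries. The haemoglobin share was 0.467 ± 0.626% in FH and 0.276 ± 0.167% in healthy libraries (permutation p = 0.43, adjusted p = 0.52), a difference of 0.191 that was 0.0237 without FH replicate 10 (2.47%), and within the second project 0.591 ± 0.728% and 0.283 ± 0.158% (exact permutation p = 0.23). The 10 most counted genes took 42.8 ± 16.2% in FH and 36.55 ± 14.1% in healthy libraries (permutation p = 0.34, adjusted p = 0.52), and within the second project 52.2 ± 8.58% and 40.2 ± 13.2% (exact permutation p = 0.043, adjusted p = 0.14). After thinning to one total, 20601 ± 1775 genes were detected in FH and 22360 ± 1402 in healthy libraries (permutation p = 0.019, adjusted p = 0.11). Within the second project the numbers were 20631 ± 1958 and 22276 ± 1550 (exact permutation p = 0.077, adjusted p = 0.14). PTPRC, as log2(CPM + 1) without TMM scaling, was 8.03 ± 0.908 in FH and 8.7845 ± 1.0007 in healthy libraries (permutation p = 0.075, adjusted p = 0.22), and 8.15 ± 1.07 and 8.97 ± 1.04 within the second project (exact permutation p = 0.13, adjusted p = 0.16). Its unadjusted p was under 0.05 on leaving out healthy replicate 1 (p = 0.048) or 10 (p = 0.039), or FH replicate 9 (p = 0.045) or 10 (p = 0.026).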

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

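The ratio test of neutrophil to T and NK cell markers, its repeat within the second project and the test with 3 cell scores were chosen only after the result was seen. Among the 10 healthy libraries, 133 measures were checked for a library far from the others, and 6 had one. Chance gives about 1 in 20 such groups. They were the mean log2 CPM of nuclear oxidative phosphorylation genes in healthy replicate 10 (4.2637, group median 3.4201) and the log2(CPM + 0.5) of 5 genes: MTND1P23 in healthy replicate 11 (1.3098, median -0.0041), CNTNAP1 in healthy replicate 6 (3.6369, median 1.7754), XKR8 in healthy replicate 1 (1.2881, median 2.2842), APOE in healthy replicate 11 (-0.063711, median -0.7858) and SIGLEC8 in healthy replicate 9 (-0.038303, median -0.85412). The 13 FH libraries were not tested this way.

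Neutrophil transcripts were higher and T and NK cell transcripts lower in FH. Library scaling is excluded as the whole cause, since it moves both sets alike within a library: the log2 ratio of the 2 sets was 2.19 ± 1.92 in FH and -2.22 ± 1.15 in healthy libraries, a difference of 4.406 (permutation p = 2.0e-05, the smallest that these resamples can give). The project make-up of the groups is excluded too, since the difference within the second project was 4.6467 (exact permutation p = 8.2e-05, the smallest possible). More neutrophil RNA in the FH preparations goes with the values: 17 of 17 further neutrophil genes rose, with a median of 2.8912 (range 1.68 to 3.58). They were read in the same libraries in which all listed neutrophil markers had risen. They widen the pattern beyond that list and are not independent support for its cause. Whether the neutrophil RNA came from more neutrophils in the blood of people with FH or from how platelets were isolated stays open, since no table here separates them.

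Of the apoptosis genes, 15 passed in FH. For the platelet share of the RNA, 6 of 15 still passed with the platelet identity score in the model, between the bounds set for and against it, and the median fold of the 15 in each gene's direction was 0.693 against 0.823 without the score. The members differed: BCL2L1 went from 0.905 ± 0.341 to 0.154 ± 0.098, BAD from 0.823 ± 0.309 to 0.197 ± 0.114 and BBC3 from 0.629 ± 0.229 to 0.207 ± 0.160. For these genes the fold shrank while the standard error did not grow, whereas 6 of 15 kept their calls. The share of platelets as the cause of the lost calls stays open for the 15 genes as a set. For the mix of platelet, T and NK cell and neutrophil RNA, the median fold with the 3 scores was 0.14788, below the bound set for it. In that fit 0 of 15 passed by edgeR. Over all genes it left 1 higher and 0 lower, against 2517 and 2950 in the main model. The lost calls are therefore not particular to apoptosis genes and cannot show the mix as their cause. For the 15 genes the median standard error went from 0.217 to 0.245. Their calls ended mainly because the folds shrank, while the scores also share variation with the group. A change of these genes within platelets of people with FH stays open.

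Mitochondrial rRNA took at most 1.25% of counts in the first project and 11.7 to 46.7% in the second, while 7SL RNA took 3.21 to 8.81% and at most 0.0113%. Another way of selecting RNA in the first project goes with this: 5 other RNAs without a poly(A) tail that had at least 100 counts were higher there by a median log2 difference of 6.5688, and 7 of the 13 RNAs listed had 0 counts. No biological explanation was tested, since projects are not groups of the design.

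In 100 splits of the 23 libraries into groups of 13 and 10, the real one included, 2 splits gave as many genes higher and 2 gave as many lower as the real split (2517 and 2950). Chance is unlikely at that share but is not excluded, since other splits reached up to 2687 genes higher and 3146 lower, above the real counts.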

How the results depend on the processing

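The fits with cell scores and the fit without the 5 libraries of lowest platelet score were chosen after the data were seen. No called gene changed sign while passing in any setting listed here. The values below are counts of genes, log2 fold changes of single genes, median log2 fold changes of lists, or differences of library measures, and the cause of each change was not tested. Counting depth limits only genes near the filter, and the intervals do not cover PCR duplicates.

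With an estimated correlation, 20 of 25 lists lost the call at unchanged medians: pro-apoptotic 0.37, anti-apoptotic 0.55, phosphatidylserine exposure 0.61, platelet receptors 0.61, granules 0.75, platelet identity 0.80, lipoprotein 0.39, mitochondrially encoded 0.97, ribosomal proteins -0.38, NF-kB 0.76, antioxidant 0.55, autophagy 0.47, immediate early 1.501, T and NK cell -1.17, B cell -0.73, monocyte 1.18, neutrophil 3.23, basophil and eosinophil 1.78, erythroid 1.03 and endothelial 1.81. With no project term, PTPRC -0.016 and proteasome -0.076 changed sign and pro-apoptotic 0.37, anti-apoptotic 0.54 and lipoprotein 0.31 lost the call. Without that term, among named genes, 10 lost the call (including FLI1, MT-ND5, RPL22, RPL32, PSMD11, SEL1L, DNAJC3, CAT, BCL2L1). In the second project only, genes lower in FH 1957 moved by over 1.5 times, BAK1 0.050 changed sign and anti-apoptotic 0.74 and lipoprotein 0.53 lost the call. There the difference in mitochondrial share of counts was 12.3 (unadjusted p = 0.048, adjusted over 6 measures p = 0.14), share of counts in the 10 largest genes was 11.9 (unadjusted p = 0.043, adjusted over 6 measures p = 0.14) and genes detected was -1644.5 (unadjusted p = 0.077, adjusted over 6 measures p = 0.14). Among named genes there, 8 lost the call (including ACAT2, RPL22, RPL32, PSMC6, PSMA5, PSMD11), 1 gained a call (MT-ND3) and 2 changed sign (including BAK1). With DESeq2 size factors in edgeR, anti-apoptotic 0.59 lost the call. With no filter on low counts, proteasome -0.057 (adjusted p = 2.0e-02) changed sign and passed in the new direction, PTPRC -0.015 changed sign, sterol synthesis -0.24, interferon-stimulated -0.19 and endoplasmic reticulum stress -0.39 gained a call and pro-apoptotic 0.30, anti-apoptotic 0.48, lipoprotein 0.32 and antioxidant 0.49 lost the call. Unfiltered, among named genes, 8 lost the call (including HLA-DRB5, FLI1, ABCA1, MT-ND5, PSMD11, SEL1L, BCL2L1). With the stricter filter on low counts, proteasome -0.041 changed sign and pro-apoptotic 0.33, anti-apoptotic 0.58, lipoprotein 0.17 and B cell -0.75 lost the call. Among named genes that filter left, 1 lost the call (BCL2L1). With PTPRC as covariate, genes higher in FH 4084 moved by over 1.5 times, proteasome -0.010 changed sign and lipoprotein 0.47 and B cell -0.74 lost the call. With this covariate, among named genes, 1 lost the call (MTND1P23) and 5 gained a call (including MT-ND3, MT-ND4L, CD22, PF4). With surrogate variables, anti-apoptotic 0.28 lost the call. Among named genes in that fit, 2 lost the call (including NDUFC1), 5 gained a call (including MT-ND3, MT-ND4L, CD22, PTPRC) and 2 changed sign. Without haemoglobin and mitochondrial genes, anti-apoptotic 0.63 and lipoprotein 0.45 lost the call. Among other named genes, 1 lost the call (PSMD11) and 1 gained a call (PF4). With limma voom and sample quality weights, oxidative phosphorylation 0.12 gained a call and B cell -0.61 lost the call. By voom, among named genes, 2 lost the call (MTND1P23, HLA-DRB5) and 4 gained a call (MT-ND3, MT-ND4L, CD22, PF4). In the DESeq2 Wald test 3332 genes were higher and 3748 lower, and 4 genes had no adjusted p. By that test, among named genes, 4 gained a call (MT-ND3, MT-ND4L, CD22, PF4).

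With the replicate block, genes higher in FH 1173 and genes lower in FH 1791 moved by over 1.5 times, proteasome -0.019 changed sign and pro-apoptotic 0.30, anti-apoptotic 0.51 and lipoprotein 0.28 lost the call. Among named genes with it, 21 lost the call (including MTND1P23, STX11, SRGN, TUBA8, FLI1, ACRBP, ABCA1, MT-ND5, NDUFA5, NDUFC1, RPL22, RPL32, PSMC6, PSMD11, SEL1L, SRXN1, HBM, CA1, BCL2L1) and 2 gained a call (including CD22). Replicate numbers were not treated as pairs: over the 10 shared numbers of this replicate block the correlation of same-numbered libraries ranged from -0.51 to 0.31, and 0 FH libraries correlated best with their own number.

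With the platelet score as covariate, genes higher in FH 1182 and genes lower in FH 683 moved by over 1.5 times, granules -0.041 and oxidative phosphorylation -0.0083 changed sign and pro-apoptotic 0.052, anti-apoptotic 0.15, phosphatidylserine exposure 0.045, platelet receptors 0.016, lipoprotein 0.17, antioxidant 0.038 and B cell -0.59 lost the call. With platelet, T and NK cell and neutrophil scores as covariates, genes higher in FH 1 and genes lower in FH 0 moved by over 1.5 times, mitochondrially encoded -0.95 (adjusted p = 2.6e-06), oxidative phosphorylation -0.23 (adjusted p = 1.3e-04), proteasome -0.16 (adjusted p = 6.1e-04), NF-kB -0.57 (adjusted p = 6.4e-04) and B cell 0.81 (adjusted p = 1.3e-04) changed sign and passed in the new direction, sterol synthesis 0.048, lipoprotein -0.0041, antioxidant -0.15, autophagy -0.033 and immediate early -0.67 changed sign, interferon-stimulated -0.42 gained a call and pro-apoptotic 0.0012, anti-apoptotic 0.096, phosphatidylserine exposure 0.053, granules 0.0083, monocyte 0.034, basophil and eosinophil 0.13 and erythroid 0.57 lost the call. Without the 5 libraries of lowest platelet score (healthy replicates 4, 5, 6 and 7 and FH replicate 10), genes higher in FH 529 and genes lower in FH 184 moved by over 1.5 times, BAX -0.085, proteasome -0.066 and interferon-stimulated 0.11 changed sign and pro-apoptotic 0.16, anti-apoptotic 0.31 and lipoprotein 0.14 lost the call. Of 102 named genes, 91 of which had passed, 70 passed with the platelet score and 3 changed sign, 0 passed with the 3 scores and 30 changed sign, and 45 lost the call without the 5 libraries. No list that changed sign and passed with the 3 scores held there with an estimated correlation (adjusted p from 0.64 to 0.74). The group term's variance inflation was 1.015 in the main model, 1.28 with the platelet score and 3.215 with the 3 scores, so the scores share variation with the group.

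Leaving out each library in turn gave these lowest and highest values, with the replicates whose removal changed the result: genes higher in FH 1862 to 4116 (moved without FH 10), genes lower in FH 1570 to 3338 (moved without healthy 4, 5, 7), ACRBP 0.85 to 1.25 (lost without FH 11, 13 and healthy 6), ABCA1 0.92 to 1.38 (lost without FH 2, 8, 13 and healthy 1, 6, 7), MT-ND5 0.95 to 1.31 (lost without FH 1, 2, 7, 8, 11, 13 and healthy 1, 4, 5, 6, 7, 9, 10, 12), MT-ND3 0.92 to 1.26 (gained without FH 4, 10 and healthy 2, 11), MT-ND4L 0.84 to 1.29 (gained without FH 4, 10 and healthy 2, 11), RPL22 -0.52 to -0.34 (lost without FH 4 and healthy 2, 4, 5, 7), RPL32 -0.58 to -0.42 (lost without FH 7, 13 and healthy 2, 4, 5, 7), PSMC6 -0.37 to -0.22 (lost without healthy 4, 5, 7), PSMA5 -0.47 to -0.29 (lost without healthy 4, 5), PSMD11 -0.38 to -0.19 (lost without FH 4, 7, 10, 13 and healthy 1, 4, 5, 7), CD22 -0.83 to -0.52 (gained without FH 3, 10, 12 and healthy 2, 11), BCL2L1 0.75 to 1.14 (lost without FH 1, 2, 5, 7, 11, 12, 13 and healthy 2, 6, 9, 11). The others were BAK1 -0.19 to 0.017 (sign changed without FH 4 and healthy 4), PF4 0.84 to 1.21 (gained without FH 4, 10 and healthy 10), PTPRC -0.014 to 0.19 (sign changed without FH 9 and healthy 10), pro-apoptotic 0.25 to 0.50 (lost without FH 1, 3, 5, 9, 13 and healthy 2, 6, 11), anti-apoptotic 0.44 to 0.75 (lost without FH 1, 2, 3, 4, 9, 10, 11, 12, 13 and healthy 1, 2, 5, 6, 7, 9), lipoprotein 0.21 to 0.46 (lost without FH 1, 3, 4, 5, 6, 8, 9, 10, 11, 12, 13 and healthy 2, 11), oxidative phosphorylation 0.043 to 0.24 (gained without FH 4, 10 and healthy 10), proteasome -0.044 to 0.12 (sign changed without FH 1, 5, 8 and healthy 1, 6, 11, 12), interferon-stimulated -0.23 to 0.089 (sign changed without FH 4, 10 and healthy 4, 5, 6), B cell -0.87 to -0.49 (lost without FH 2, 6, 7, 8, 9, 11, 13 and healthy 1, 9, 10, 12), mitochondrial share of counts 1.67 to 7.62, haemoglobin share of counts 0.024 to 0.22, PTPRC level -0.91 to -0.59 (p under 0.05 without FH 9, 10 and healthy 1, 10). Over all fits that left out 1 library, 66 of 2338 values of the named genes lost the call, 18 gained one and 8 changed sign.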

Other observations

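The gene families here were chosen after the data were seen, and 2 of the 6 formyl peptide and anaphylatoxin receptors are also in the lists of the report. All 7 GIMAP genes, GTPases of lymphocytes, fell in FH, with a median log2 fold change of -1.01, among them GIMAP6 (-1.01 ± 0.17) and GIMAP2 (-0.85 ± 0.16). Of 9 leukocyte immunoglobulin-like receptors 8 rose, with a median of 1.19, including LILRB3 (2.59 ± 0.49) and LILRA5 (1.71 ± 0.38), although these genes have near-identical paralogs and their counts are uncertain. Of 6 formyl peptide and anaphylatoxin receptors 4 rose, with a median of 2.63: FPR1 (2.92 ± 0.56), FPR2 (3.03 ± 0.61), C5AR1 (2.73 ± 0.56) and C5AR2 (2.52 ± 0.42). Camera gave adjusted p-values of 2.4e-05, 1.1e-04 and 5.1e-04 for these 3 families, and 0.19 for each with an estimated correlation. With the platelet, T and NK cell and neutrophil scores in the model their medians were -0.49, -0.38 and -0.35, and 0 of their genes passed by edgeR. Of 478 ZNF genes 158 fell and 18 rose, with a median of -0.48 (camera adjusted p = 2.0e-07, or adjusted p = 0.30 with an estimated correlation), and with the 3 scores their median was 0.18 and 0 passed.

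Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, had a positive median change in FH (0.98). Of 47 tested, 13 rose, 0 fell, the others did not pass, and 44 lay above 0. Camera gave an adjusted p of 1.2e-05, or 0.34 with an estimated correlation, and fry gave an adjusted p of 0.051. Among those that rose were H4C8 (1.92 ± 0.49) and H2BC5 (1.46 ± 0.42), and near-identical copies make single histone genes uncertain. With the platelet identity score in the model, the family's median was -0.0041 and 0 passed by edgeR. With the 3 scores the family's median was -0.83 and 0 passed.

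FH replicates 3 and 4 were the closest pair of libraries of one group, with a chi-square per degree of freedom of 46.8, against 96.6 for the next pair and a median of 886. Both were kept as separate libraries among the 13, and whether they come from separate people is not given in the sources used here. Without FH replicate 3, 2643 genes were higher and 3252 lower, and without FH replicate 4 the counts were 3491 and 2559.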
